A study of Arabidopsis thaliana with 6 samples.

How the data were processed

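RNA was sequenced from siliques, the seed pods of Arabidopsis thaliana, in 6 libraries: 3 from wild type (WT) plants and 3 labelled shp1 shp2 mrpl1. Plants were grown on Murashige and Skoog medium under long days, and mRNA was purified from total RNA before library preparation, per the labels' protocols. Groups and replicate numbers came from the genotype and the titles in the labels. Nothing in the labels says that the 3 samples of a group came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

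The deposited table held 1 column of estimated counts per library over 27628 transcript identifiers, each for a different locus. The submitters' processing notes name Trimmomatic 0.39, FastQC 0.11.9, HISAT2, featureCounts 1.6.3 and DESeq2, without saying which step each served. The genome build, the annotation and any strand setting were not given in the sources used here. Between 2.95% and 3.47% of the deposited values per library were not whole (tolerance 1e-09), so the table was treated as estimated counts and rounded to whole numbers before testing. How reads that fit several loci were divided was not given in the sources used here.

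Of the 27628 identifiers, 27419 matched a transcript of the TAIR10.1 RefSeq annotation. Gene symbols, products, transcript lengths and coordinates were taken from that match. Where a gene's usual name differed from the reference symbol, both are given. Genes taken by the naming rule were checked against TAIR10.1 for overlap with other annotated genes and for 50-base windows shared with other transcripts. Of the 61 genes checked, 16 overlapped another gene and 12 shared a window. These are uncertain where reads could have been split or where strand was not used.

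The main comparison, labelled shp1 shp2 mrpl1 minus WT, was fitted with edgeR 4.0.16 in R 4.3.3 on the rounded counts, with TMM scaling, the default expression filter (minimum count 10, minimum total count 15), robust dispersion and the quasi-likelihood test. Genotype was the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a second count required a change of at least 2-fold. Standard errors were the log2 fold change divided by the square root of the test's F value. Levels are edgeR's CPM after TMM scaling, given as mean ± SD over the 3 libraries of a group.

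A set of 20 gene lists was fixed before the data were examined. Of their 347 entries, 337 were kept, 4 of them at the only other locus with the listed symbol, and 10 were left out because the reference gave the symbol to no single locus. Each list was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists, and again with an estimated correlation. With an estimated correlation camera also judges its statistic on the few residual degrees of freedom, which by itself raises p-values. For each list the number of members called over all genes is given beside the number adjusted over the list alone. MRPL1 was taken as AT2G42710 because its reference product is a ribosomal protein of the L1 family; the labels give no locus.

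The genes named in the text followed a rule fixed before the data were examined. It took the 3 genes of the genotype, the 6 largest increases and 6 largest decreases among called genes with an average log2 CPM of at least 1 and no overlap between groups, and up to 2 members of each list with the smallest adjusted p. The lists for valve margin, lignin, mitochondrial chaperones and the mitochondrial dysfunction stimulon gave up to 4 members each. Further list members and families are named to describe a group and were chosen after their values were seen.

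Neighbours of the mutated loci, 200 genes on either side, were compared with other nuclear genes by Fisher's exact test, two-sided. Organelle shares of counts were compared by an exact permutation test over 20 assignments, two-sided, whose smallest possible p is 0.1. Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, library totals, the DESeq2 1.42.0 test, limma voom with quality weights, 2 other expression filters, the replicate number as a block, removal of organelle genes or of the 10 most abundant genes, and leaving out each library. For the lists they also included an estimated correlation and fry, and for the neighbours windows of 100 and 400 genes and counts without the neighbours. Corrections for transcript length and GC content, removal of loci with fractional counts, list members at the listed loci and removal of WT replicate 1 with mutant-labelled replicate 1 were chosen after seeing the data.

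The fit was tested on simulated counts drawn from the means, library sizes and dispersions of the real data, over 20681 genes. At 3 libraries per group it recovered 32.7% of 49 genes changed by 1.3-fold, 81.2% of 48 changed by 1.5-fold, 91.7% of 48 changed by 2-fold and 100% of 50 changed by 4-fold. Of its 175 calls, 12 (6.86%) were of unchanged genes. The real data gave 1865 calls, and the simulated genes varied independently, without the axis tied to transcript length described below. Its recovery and its share of unchanged genes may therefore not carry over to the real data. Library totals lay between 17857873 and 21603816 estimated counts.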

Results

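SHP1 and SHP2 are MADS-box transcription factors that specify the valve margin, the strip of cells along which a silique opens, and MRPL1 is a protein of the mitochondrial ribosome. The series compared siliques of WT with siliques labelled as the triple mutant shp1 shp2 mrpl1, and its title ties SHP to fruit shell thickness and to the mitochondrial unfolded protein response. There were 3 libraries per group. WT replicates 1 to 3 held 20883220, 21603816 and 19969915 estimated counts, and mutant-labelled replicates 1 to 3 held 20563995, 17857873 and 20957661. Of 27628 loci, 1898 had no count in any library, and 20827 passed the expression filter.

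The genes named in the genotype did not all fall in the libraries labelled shp1 shp2 mrpl1. SHP1 was lower by a log2 fold change of −0.51 (SE 0.087; adjusted p = 0.00242, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level was 42.3, 37.5 and 43.5 CPM in WT replicates 1 to 3 and 26.9, 31.5 and 28.4 CPM in mutant-labelled replicates 1 to 3, so that about 70% of the WT transcript remained. SHP2 stood at 107 ± 2.86 CPM in WT and 106 ± 3.79 CPM in the mutant-labelled libraries (SD, n = 3 each), a log2 fold change of −0.01 (SE 0.065; edgeR adjusted p = 0.937). MRPL1 (AT2G42710) stood at 14.5 ± 1.35 CPM in WT and 17.1 ± 1.05 CPM in the mutant-labelled libraries, a log2 fold change of 0.24 (SE 0.099; edgeR adjusted p = 0.172). Every direction below is therefore drawn between libraries as labelled, because SHP2 and MRPL1 do not show the genotype in these counts.

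In TAIR10.1, SHP1 (AT3G58780) has 7 exons on the plus strand of chromosome 3, from 21738160 to 21742517. SHP2 (AT2G42830) has 7 exons on the plus strand of chromosome 2, from 17820114 to 17824013, and MRPL1 has 10 exons on the same strand, from 17782308 to 17785090. Antisense genes overlap SHP1 by up to 564 bases and SHP2 by 1756 bases, so without a stated strand setting their counts can include antisense reads. No 50-base window of the SHP1 or SHP2 transcript occurred in another transcript of the table. The mutated sites were not given in the labels used here.

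**Figure D1:**
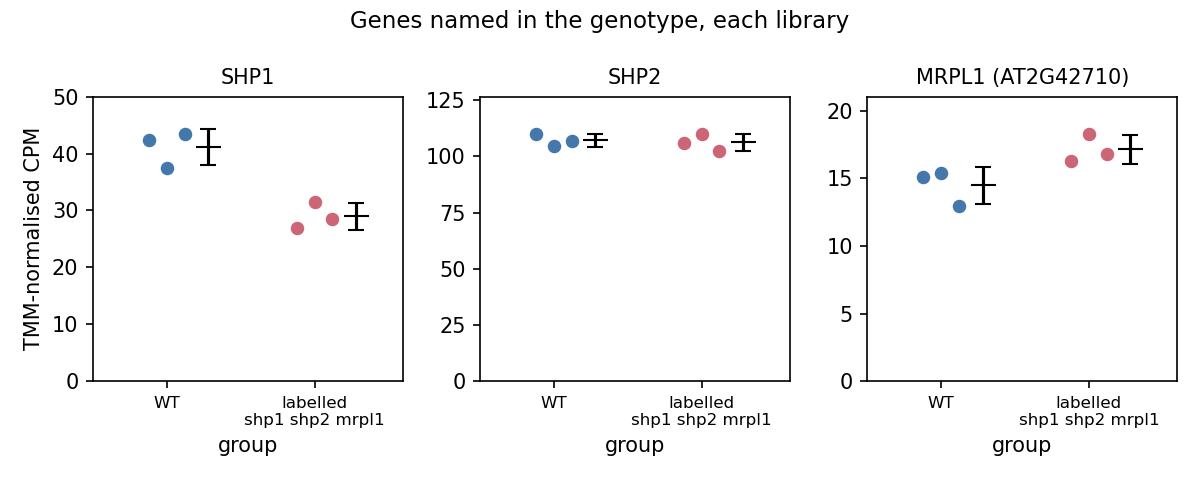
Level of SHP1, SHP2 and MRPL1 in each library, in TMM-normalised CPM on axes that start at 0, for WT and for libraries labelled shp1 shp2 mrpl1 (points are libraries, bars the mean ± SD, n = 3). SHP1 lies between 37.5 and 43.5 CPM in WT and between 26.9 and 31.5 CPM in the mutant-labelled libraries, while the ranges of the groups overlap for SHP2, 104 to 110 CPM in WT and 102 to 110 CPM in the mutant-labelled libraries.

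Across the silique transcriptome, 1018 genes were higher and 847 lower in the mutant-labelled libraries, 8.95% of those tested, and 175 rose and 75 fell at least 2-fold. The largest changes below were ranked among called genes with an average log2 CPM of at least 1 and no overlap between groups. MRD1, a gene named for its response to methionine overaccumulation, fell furthest of these, from 19.6 ± 2.47 to 0.648 ± 0.039 CPM, a log2 fold change of −4.90 (SE 0.171). It overlaps HEI10, a gene for a meiotic crossover protein, by 1446 bases on the other strand. HEI10 had a log2 fold change of −1.53, and the values of this pair are uncertain for that reason. The other large decreases were RRTF1, a redox-responsive transcription factor (−2.04), the WD40 repeat gene AT1G18830 (−1.94), AT1G62981 (−1.62) and the sugar transporter gene SWEET14 (−1.59). RRTF1 also overlaps antisense genes. Outside this ranking AT5G52020 had a larger fall than RRTF1, −2.18, at an average log2 CPM of 0.71. The largest increases were AT3G29633, of unknown function (3.25), the zinc transporter-like gene AT2G04620 (3.15), the hydrolase gene AT4G17470 (2.56), AT2G23400 (2.40), the myrosinase-binding protein gene MBP1 (1.93) and the oxygenase gene AT5G54000 (1.88). AT2G04620 went from 1.59 ± 0.404 to 14.1 ± 1.27 CPM and overlaps an antisense gene. AT2G23400 shared 8.19% of its 50-base windows with another transcript. Each of these 12 genes had an adjusted p below the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the libraries of the groups did not overlap. Of the 1865 called genes, 1857 had no overlap between groups, as did 25.9% of all tested genes, where chance gives 10%.

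The share of called genes that were higher was 54.6%, and 65.1% when libraries were scaled by their totals alone. In each group replicate 1 stood apart from its mates: the chi-square per degree of freedom between WT replicate 1 and the others was 11.96 and 12.08, against 2.54 between WT replicates 2 and 3, and for the mutant-labelled libraries it was 9.16 and 7.69 against 2.89. Log2 fold changes also declined with transcript length (Spearman's rho −0.25 across 20733 genes, which are not independent replicates). On the second principal component each replicate 1 lay on the side of the other group's replicates 2 and 3, so leaving out both lines genotype up with that axis. Higher and lower genes numbered 3191 and 3301 without both replicates 1, where rho was −0.45, and 1750 and 1544 after a correction for length. Leaving out 1 library moved these counts by over 1.5 times for WT replicate 1 (1534 higher, 1468 lower), WT replicate 2 (670, 539), WT replicate 3 (608, 476), mutant-labelled replicate 3 (578, 426) and, for lower genes, mutant-labelled replicate 2 (522).

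Genes for lignin and secondary cell walls, which harden the tissue around the valve margin and the vessels of the silique, were lower as a group in the mutant-labelled libraries by camera at the preset correlation (adjusted p = 8.84e-34). With an estimated correlation the list did not pass (camera adjusted p = 0.0523). Of 33 tested members, 28 fell and 5 were not called. The 28 lower calls became 19 with the replicate block and 25 without WT replicate 2 or 3 or mutant-labelled replicate 2. They became 27 without mutant-labelled replicate 1 or 3 and stayed 28 without WT replicate 1. The list's median log2 fold change was −0.53, or 0.695 times the WT level. The largest falls in the list were in MYB103 (−0.88, SE 0.11), a regulator of secondary walls, and LAC17 (−0.86, SE 0.13), a laccase that polymerises lignin. PAL1, which opens the phenylpropanoid pathway, went from 510 ± 17.7 to 308 ± 10.2 CPM (−0.73, SE 0.06; edgeR adjusted p = 9.22e-06).

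The fall covered successive steps of the pathway. 4CL1, which activates 4-coumarate, went from 344 ± 13.7 to 204 ± 10.6 CPM (−0.75), PAL4 from 316 ± 13.2 to 195 ± 6.63 CPM (−0.69) and the methyltransferase gene OMT1 from 514 ± 24.5 to 339 ± 1.31 CPM (−0.60), each called by edgeR's quasi-likelihood test. The cellulose synthase genes of secondary walls fell as well: CESA4 by 0.82, IRX3 by 0.71 and IRX1 by 0.66 on the log2 scale. Among regulators, NAC073 fell by 0.74, MYB85 by 0.61, MYB63 by 0.50 and MYB58 by 0.46. The laccase genes IRX12 and LAC11 fell by 0.67 and 0.78. The members not called included MYB46 (−0.32, edgeR adjusted p = 0.306), KNAT7 (−0.01) and the xylan synthesis gene IRX9 (0.26, edgeR adjusted p = 0.0718). Adjusted over the list alone, 29 members were lower and 1 higher, and after the length correction the median was −0.57.

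**Figure D2:**
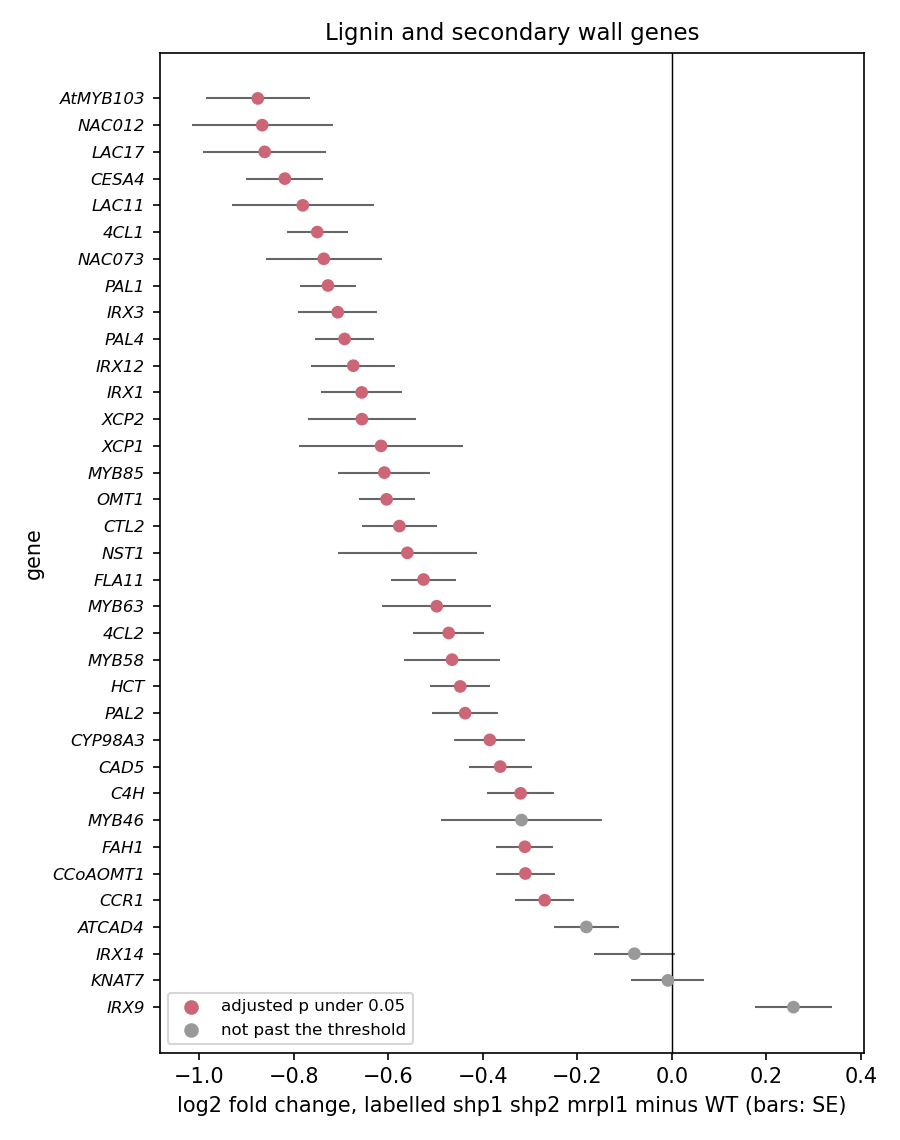
Log2 fold change (labelled shp1 shp2 mrpl1 minus WT, bars are SE) of the 33 tested lignin and secondary wall genes and of NAC012 and NST1 from the valve margin list, with called genes in red. Of the 33, 28 lie below 0 and past the threshold, and IRX9 lies above 0 at 0.26.

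Among valve margin and carpel genes, 7 of 25 tested members fell, SHP1 included, and 1 rose. Several of the lower calls were lost when single libraries were left out. SHP1 is named in the genotype, so its fall counts toward this list's calls and set tests without being a separate change. NAC012, also known as NST3 or SND1, a master switch of fibre wall thickening, went from 9.42 ± 0.22 to 5.16 ± 1.16 CPM (−0.87, SE 0.149; edgeR adjusted p = 0.00242), and its relative NST1, which acts in the valve margin, fell by 0.56. YAB3, a valve identity gene, fell by 0.32 (edgeR adjusted p = 0.0268) and FUL, listed as AGL8, by 0.30. GA3OX1, for gibberellin synthesis, fell by 0.47 and AS1, a leaf and valve polarity gene, by 0.28. The polygalacturonase gene ADPG2, listed as PGAZAT, which acts in pod opening, went from 2.53 ± 0.442 to 4.11 ± 0.214 CPM (0.69; edgeR adjusted p = 0.0244). IND (0.31, edgeR adjusted p = 0.257) and ALC (−0.02), which act downstream of SHP in the margin, and the related enzyme gene ADPG1 (0.21) were not called. As a set, the list did not pass camera's threshold (adjusted p = 0.0668, and adjusted p = 0.205 with an estimated correlation; median −0.02), and adjusted over the list alone 7 members were lower and 2 higher. It passed downward without WT replicate 2 (camera adjusted p = 0.0362) and without mutant-labelled replicate 2 or 3 (camera adjusted p = 0.0463 and 0.0453), with no filter (camera adjusted p = 0.0467) and after the length correction (camera adjusted p = 0.0482, median −0.10). The 7 lower calls became 3, 2, 4, 3 and 3 without WT replicate 2, WT replicate 3 and mutant-labelled replicates 1, 2 and 3 in turn, and the 1 higher call became 2 without mutant-labelled replicate 1; DESeq2 called 3 lower and 0 higher. Limma voom called 9 lower and 2 higher, the length correction 7 and 3, and the fit without both replicates 1 gave 10 and 4. The calls of ADPG2 and YAB3 were lost without WT replicate 3 and without mutant-labelled replicate 2 or 3, and that of YAB3 also without WT replicate 2 (edgeR adjusted p between 0.0627 and 0.135). In these fits, which had fewer libraries, the log2 fold change stayed between 0.57 and 0.72 for ADPG2 and between −0.31 and −0.30 for YAB3.

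Genes of the mitochondrial unfolded protein response, which the title names, were not shifted as a set. Of 18 genes in the list of mitochondrial chaperones and proteases, 0 were called by edgeR's quasi-likelihood test, with 2 at an unadjusted p under 0.05, 0 called by DESeq2 and 3 by limma voom. The median log2 fold change was −0.01. The smallest adjusted p values belonged to the protease gene FTSH10 (−0.24, SE 0.08; edgeR adjusted p = 0.0867), the prohibitin gene PHB3 (0.23; edgeR adjusted p = 0.124), CLPX (−0.12) and EMB1241 (0.14), the last placed by its symbol at AT5G17710, which is not the listed mitochondrial locus. FTSH10 overlaps antisense genes by up to 2852 bases, so its count is uncertain. The chaperonin gene HSP60 had a log2 fold change of 0.02 and the heat shock gene MTHSC70-2 one of −0.03. Adjusted over the list alone, 0 members were called, and camera gave adjusted p = 0.805 (adjusted p = 0.887 with an estimated correlation). The list lacked HSP23.5 (0.22) and HSP23.6 (0.60, edgeR adjusted p = 0.165), small heat shock genes whose symbols the reference does not give to their listed loci. FTSH10 and PHB3 were called without WT replicate 1 (edgeR adjusted p = 0.00637 and 0.0278), and 3 of the 18 were higher and 7 lower without both replicates 1, fits in which log2 fold changes followed transcript length more closely (Spearman's rho −0.36 and −0.45 across genes, against −0.25). PHB3 was also called after the length correction (0.25, edgeR adjusted p = 0.0216), the 1 higher call of the list there.

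The mitochondrial dysfunction stimulon, genes that respond when mitochondrial function is impaired, was not shifted as a set either. Of 14 tested members, 2 fell: the glutathione transferase gene GSTU25, at 0.890 ± 0.088 and 0.296 ± 0.067 CPM (−1.55; edgeR adjusted p = 0.0166), and the carrier gene DIC2 (−0.28; edgeR adjusted p = 0.0318). ERF71 (0.82) and ST2A (−0.16) were not called, nor was AOX1A, the classical marker of this response (0.11, SE 0.08; edgeR adjusted p = 0.474). Camera gave adjusted p = 0.341 (adjusted p = 0.534 with an estimated correlation), and 2 members were lower when adjusted over the list alone. The name rule left out UPOX (0.48, edgeR adjusted p = 0.0639), AT12CYS-2 (0.35) and NAC013 (−0.07), and moved ST2A away from AT2G03760, which was higher (0.73, edgeR adjusted p = 0.00407). With these at their listed loci, 1 of 17 members rose and 2 fell (camera adjusted p = 0.916). Of 6 genes for mitochondrial ribosomal proteins, MRPL1 included, 0 were called by edgeR's quasi-likelihood test, 1 had an unadjusted p under 0.05, DESeq2 called 0 and limma voom 1. Their median was 0.13 (camera adjusted p = 0.341; adjusted p = 0.534 with an estimated correlation), MRPL11 had a log2 fold change of 0.20, and 0 were called when adjusted over the list alone. GSTU25 and DIC2 lost their calls without WT replicate 2 and without mutant-labelled replicate 2 or 3, and DIC2 also without WT replicate 3 or mutant-labelled replicate 1 (edgeR adjusted p between 0.0585 and 0.108).

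Unfolded protein genes outside the mitochondria were mixed. In the endoplasmic reticulum list, 0 of 12 were called by edgeR's quasi-likelihood test, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. The length correction gave 1 higher there, SHD (0.21, edgeR adjusted p = 0.00721), and leaving out both replicates 1 gave 2 higher and 2 lower. In the main comparison SHD (0.13) and CRT1a (0.13) had the smallest adjusted p there, and camera gave adjusted p = 0.805 (adjusted p = 0.890 with an estimated correlation). Cytosolic heat shock genes were higher as a group by camera (median 0.17; adjusted p = 0.000215, and adjusted p = 0.119 with an estimated correlation). Of 12 tested, 2 rose, the small heat shock protein genes HSP17.4, from 102 ± 4.59 to 210 ± 14.1 CPM (1.05), and HSP17.6A, from 63.9 ± 6.46 to 157 CPM (edgeR adjusted p = 3.98e-06). HSP17.4 overlaps antisense genes by up to 453 bases, so its count is uncertain. HSP101 (−0.09) and HSP70 (−0.02) were not called. Adjusted over the endoplasmic reticulum list alone 0 were called, and adjusted over the cytosolic list alone 3 were higher.

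Photosynthesis genes lay above other genes by camera at the preset correlation (adjusted p = 4.19e-05) but not with an estimated correlation (adjusted p = 0.434). All 32 had a positive log2 fold change with a median of 0.17, and 6 rose. PORB, for chlorophyll synthesis, went from 60.1 ± 4.24 to 79.3 ± 0.765 CPM (0.40; edgeR adjusted p = 0.0038), and CAB1, a light-harvesting protein gene, rose by a log2 fold change of 0.30 (edgeR adjusted p = 0.0135) but shared 17.0% of its windows with its close copies. Adjusted over the list alone 21 were higher, and the length-corrected median was 0.12. The 6 higher calls became 15, 1 and 1 without WT replicates 1, 2 and 3 in turn, and 11, 2 and 1 without mutant-labelled replicates 1, 2 and 3. Limma voom called 25 and the fit with the replicate block 0. Circadian clock genes were lower as a group (median −0.21; camera adjusted p = 0.00205, and adjusted p = 0.205 with an estimated correlation): 2 of 15 fell, PRR9 (−0.42), which shared 33.7% of its windows with another transcript, and LHY (−0.46), and 7 were lower when adjusted over the list alone. The 2 lower calls became 8 without WT replicate 1, 1 without WT replicate 3, 4 without mutant-labelled replicate 1, 9 without both replicates 1 and 8 with limma voom. They also became 4 with DESeq2 size factors, 3 with upper-quartile scaling, 3 with the DESeq2 test and 5 with no filter, and stayed 2 with library totals and with the CPM filter. The call of CAB1 was lost without WT replicate 2 or 3 or mutant-labelled replicate 3, and that of LHY without WT replicate 3 (edgeR adjusted p between 0.0533 and 0.0953).

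Several seed storage genes were lower in the mutant-labelled siliques. Of 20 embryo genes tested, 7 fell and 2 rose, with a median of −0.17. The list was lower by camera at the preset correlation (adjusted p = 0.0114) but not with an estimated correlation (adjusted p = 0.205), without WT replicate 1 (adjusted p = 0.0673) or without both replicates 1 (adjusted p = 0.171). Leaving out the 10 most abundant genes took members from the list itself, and the 13 that were left had a median of −0.12 (camera adjusted p = 0.791). The cruciferin gene CRU2, for a major storage protein, went from 24781 ± 1385 to 18630 ± 465 CPM (−0.41; edgeR adjusted p = 0.000575). CRU3 fell by 0.42, CRA1 by 0.31, SESA2 by 0.33 and the oleosin gene OLEO1 by 0.35. GEA6, the desiccation gene EM6, rose from 126 ± 24.3 to 333 ± 53.7 CPM (1.40; edgeR adjusted p = 0.000493), and LEC1, an early embryo regulator, rose by a log2 fold change of 0.29. The 10 most abundant genes took 21.0% ± 0.445 of counts in WT and 18.16% ± 0.39 in the mutant-labelled libraries. Adjusted over the list alone 11 were lower and 2 higher, and the length-corrected median was −0.24. The 2 higher calls became 1 without WT replicate 2 or 3 or mutant-labelled replicate 2 or 3.

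Other tissues of the silique gave smaller groups. In the seed coat and endosperm list 3 of 18 rose and 1 fell: RGE1, an endosperm regulator, rose by a log2 fold change of 0.63 and the imprinted endosperm gene PHE1 fell by 1.14, while PHE1 shared 6.89% of its windows with a close copy. Camera gave adjusted p = 0.593 for that list (adjusted p = 0.6001 with an estimated correlation), with 3 higher and 1 lower when adjusted over the list alone. The 3 higher calls became 1 without WT replicate 2, WT replicate 3 or mutant-labelled replicate 1. Of 7 pollen, stamen and petal genes, VGD1, a pollen tube pectin methylesterase gene, rose (0.62), and PPME1 was not called (1.14; edgeR adjusted p = 0.0939). That list passed camera with a median of 0.62 (adjusted p = 0.0477, and adjusted p = 0.205 with an estimated correlation), 3 were higher when adjusted over the list alone, and VGD1 and PPME1 shared windows with other transcripts. The camera call was lost without WT replicate 1 or 3, without mutant-labelled replicate 1 or 3 (adjusted p between 0.0612 and 0.109), and without both replicates 1 (adjusted p = 0.209). It was also lost with library totals, DESeq2, limma voom, no filter, the 10 most abundant genes left out, the length correction (camera adjusted p between 0.0515 and 0.119) and the CPM filter (camera adjusted p = 0.154, where the median was 0.11).

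Genes of wall loosening, ageing and division included several increases. XTH24, an enzyme that remodels xyloglucan, went from 326 ± 5.87 to 499 ± 7.02 CPM (0.62; edgeR adjusted p = 2.06e-05), and PME3, a pectin methylesterase gene, rose by a log2 fold change of 0.63. In that list 3 of 14 rose, also 3 when adjusted over the list alone, and camera did not pass the threshold (adjusted p = 0.0552; adjusted p = 0.352 with an estimated correlation). That list passed without WT replicate 2 or mutant-labelled replicate 2 (camera adjusted p = 0.0266 and 0.0213), and with the DESeq2 fit, library totals, no filter, the length correction or the GC correction (camera adjusted p = 0.0192, 0.0427, 0.0365, 0.0257 and 0.0491). In the senescence list 5 of 13 rose and 1, SAG12 (−0.28), fell. WRKY53 rose by a log2 fold change of 0.84 and the asparagine synthetase gene ASN1 by 0.69 (median 0.22; camera adjusted p = 0.00342, and adjusted p = 0.285 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone). WRKY53 overlaps an antisense gene by 341 bases. The 5 higher calls became 3 without WT replicate 2 or 3 or mutant-labelled replicate 2 or 3, and the lower call was lost without mutant-labelled replicate 2. Of 14 cell cycle genes, SYP111, the cytokinesis syntaxin KNOLLE, rose by 0.49 and CDKB2;1 by 0.33 (median 0.16; camera adjusted p = 0.0333, and adjusted p = 0.205 with an estimated correlation; 2 adjusted over the list alone). SYP111 overlaps an antisense gene by 464 bases. The cell cycle call was lost without WT replicate 1 (camera adjusted p = 0.0673), without mutant-labelled replicate 1 (camera adjusted p = 0.0803), without both (camera adjusted p = 0.171) and with limma voom (camera adjusted p = 0.0529). CDKB2;1 was not called without WT replicate 2 or 3 or mutant-labelled replicate 2 or 3 (edgeR adjusted p between 0.0619 and 0.131).

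Hormone genes went in both directions. In the jasmonate list the vegetative storage protein genes VSP1, from 82.6 to 291 CPM (1.82), and VSP2, from 350 to 812 CPM (1.21), rose, as did JAZ10 and AOC3, while MYC2, the central transcription factor of the pathway, fell by 0.67 and JAZ5 by 0.44. The median of the 13 tested was −0.10, the opposite sign to camera's upward call (adjusted p = 0.0168, and adjusted p = 0.205 with an estimated correlation), with 4 higher and 5 lower adjusted over the list alone. The camera call was also lost with limma voom (adjusted p = 0.829), the replicate block (adjusted p = 0.0531) and without loci with fractional counts, where the test turned downward (adjusted p = 0.0785). The 2 lower calls became 1 without WT replicate 3 or mutant-labelled replicate 3. In the abscisic acid and cold list the dehydrin gene RAB18 went from 518 ± 14.9 to 909 ± 49.8 CPM (0.81), LTI65 rose by 0.63 on the log2 scale, and NCED3, for abscisic acid synthesis, fell by 1.13. Camera gave adjusted p = 0.581 for its 13 genes (adjusted p = 0.6001 with an estimated correlation), upward where the median was −0.07, and 2 were higher and 2 lower adjusted over the list alone.

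In the ethylene list ERF2 (−0.80), ERS2 (−0.35) and ACS6 (−0.37) fell among 14 tested (camera adjusted p = 0.210; adjusted p = 0.352 with an estimated correlation; 2 higher and 3 lower adjusted over the list alone). In the auxin list 3 of 14 tested fell, the synthesis genes YUC4 (−0.69) and TAA1 (−0.31) among them, and GH3.3 rose (0.26) (camera adjusted p = 0.955; adjusted p = 0.955 with an estimated correlation; 3 higher and 3 lower adjusted over the list alone). Of 12 salicylate and defence genes, 0 were called by edgeR's quasi-likelihood test, 5 had an unadjusted p under 0.05, DESeq2 called 0, limma voom 1 and the length correction 2; ALD1 had a log2 fold change of 0.23 and CBP60G one of 0.97 (camera adjusted p = 0.243; adjusted p = 0.352 with an estimated correlation; 0 adjusted over the list alone). The 3 lower ethylene calls became 1 without mutant-labelled replicate 2, and the 3 lower auxin calls became 1 without mutant-labelled replicate 3. The 1 higher auxin call became 0 without WT replicate 2 or 3 or mutant-labelled replicate 2 or 3, and 2 without mutant-labelled replicate 1. ERS2 was not called without WT replicate 3 or mutant-labelled replicate 2, nor YUC4 without mutant-labelled replicate 3 (edgeR adjusted p between 0.0511 and 0.0585).

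**Figure D3:**
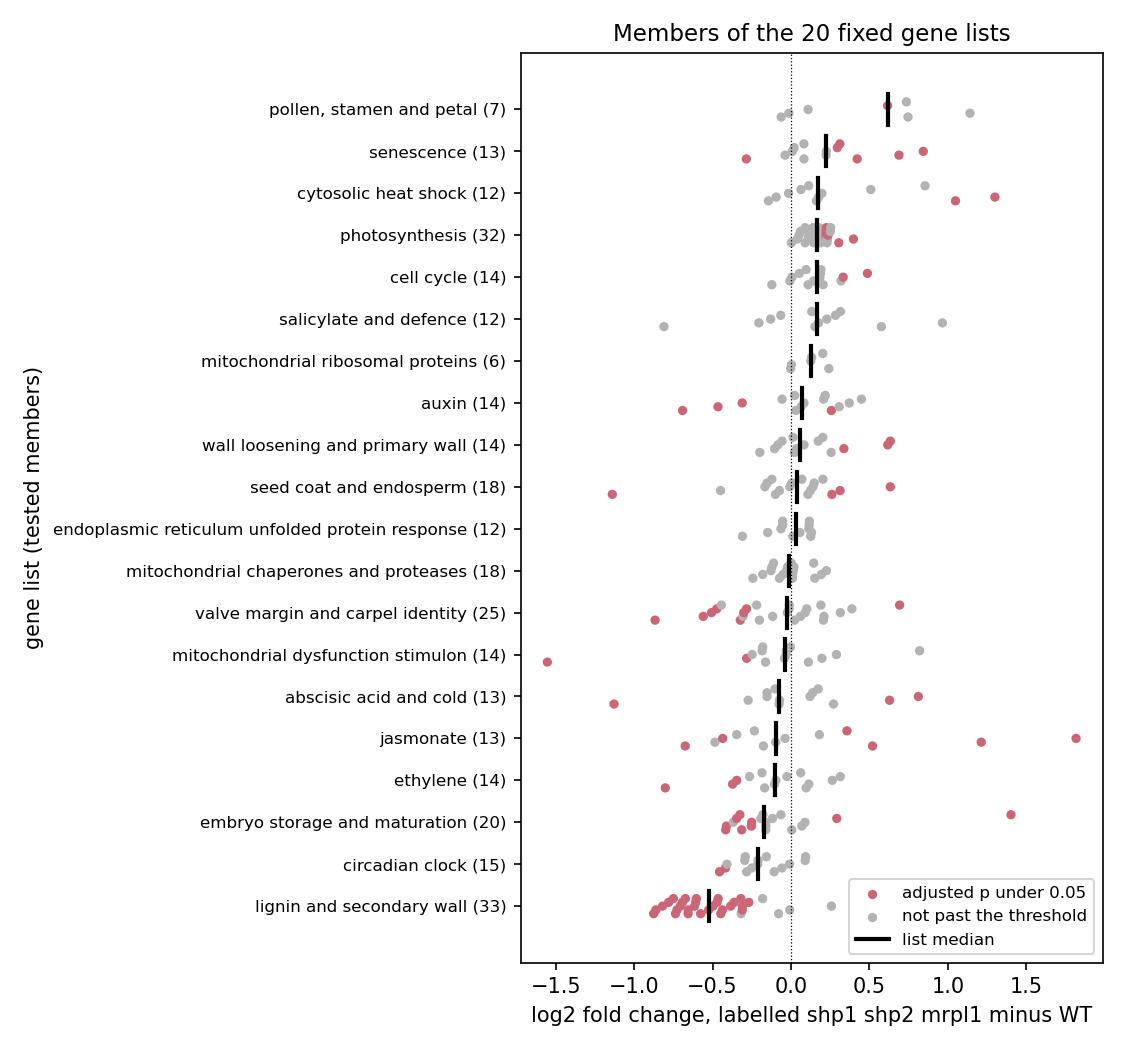
Log2 fold change (labelled shp1 shp2 mrpl1 minus WT) of each tested member of the 20 fixed gene lists, with the number tested in brackets, called genes in red and the list median as a black bar. The lignin and secondary wall list has the lowest median, −0.53, and the mitochondrial chaperone list has a median of −0.01.

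By camera, 9 of the 20 lists passed the threshold at the preset correlation, 6 upward and 3 downward, and 0 did with an estimated correlation. By fry, which does not compare a list with other genes, 12 passed, including valve margin (adjusted p = 0.012), salicylate and defence (adjusted p = 0.0116) and wall loosening (adjusted p = 0.0474). Genes near the mutated loci were not called more often than others. Among 645 tested genes within 200 genes of SHP1 or of SHP2 with MRPL1, 48 (7.44%) were called, against 1814 of 20084 (9.03%) elsewhere in the nuclear genome. The odds ratio was 0.81 (95% interval 0.588 to 1.09; Fisher's exact test, two-sided, p = 0.183). Mitochondrial genes took 0.00862% ± 0.00146 of counts in WT and 0.012% ± 0.00343 in the mutant-labelled libraries (SD, n = 3 each; exact permutation test, two-sided, p = 0.3), and chloroplast genes 0.0182% ± 0.00593 and 0.0288% ± 0.0158 (exact permutation test, p = 0.4), where 3 against 3 libraries cannot give a p below 0.1. The chloroplast share was 0.0471% in mutant-labelled replicate 1, against 0.0206% and 0.0189% in replicates 2 and 3. With single libraries left out, the group difference ran from 0.00153 to 0.0156 percentage points for chloroplast genes and from 0.0014 to 0.00441 for mitochondrial genes.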

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

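The replicate block, the scalings, filters, other tools and single libraries left out were fixed before the data were examined. The length and GC corrections, loci with fractional counts left out, the members at the listed loci and the removal of both replicates 1 were chosen after seeing the data. Over all alternatives, values of the genes checked kept direction and side of the threshold in 1145 comparisons, lost the call in 43, gained it in 18 and changed sign in 4. List tests did so in 405, 30, 15 and 10. The fall of SHP1 stayed called throughout, between −0.57 and −0.46 with single libraries left out.

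DESeq2 did not call ADPG2, YAB3, GSTU25, DIC2 or CDKB2;1 (adjusted p between 0.0513 and 0.0691). Limma voom with quality weights gave 2137 genes higher and 1986 lower, and the length correction 1750 and 1544. Leaving out single libraries gave 578 to 1534 higher and 426 to 1468 lower genes. Without both replicates 1, counts were 3191 higher, 3301 lower, 266 higher and 124 lower at least 2-fold, with MRPL1 called at 0.30. Fewer libraries took part in these fits, and the cause of the other differences was not tested. With the estimated correlation the lignin list was not called (camera adjusted p = 0.0523) and 0 lists passed the threshold. That setting also uses fewer degrees of freedom, so these losses do not measure correlation alone. Cytosolic heat shock lost its call (camera adjusted p from 0.000215 to 0.119) at an estimated correlation of −0.038, below the preset 0.01. With single libraries left out, the lists past the threshold numbered 6 to 11. SHP2 changed sign near 0, at 0.0224 with library totals, 0.00774 without both replicates 1, and −0.0386 to 0.0122 with single libraries left out. Lists far from the threshold also changed direction, given here as camera adjusted p. Auxin did at 0.991 with the CPM filter, 0.986 with the length correction, 0.792 without fractional loci and within 0.869 to 0.955 with single libraries left out. The mitochondrial chaperone list did at 0.654 with the length correction and within 0.481 to 0.951 with single libraries left out. The endoplasmic reticulum list did within 0.607 to 0.993, and the mitochondrial stimulon at 0.916 with members at the listed loci. The jasmonate list lost its upward call and turned downward without fractional loci (0.0785), which include VSP1 and VSP2, and lost the call with limma voom (0.829) and the replicate block (0.0531).

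The replicate block gave 475 genes higher and 320 lower and an odds ratio of 1.01 near the mutated loci. Same-numbered libraries deviated oppositely (correlations −0.36, −0.19 and −0.12) and 0 of the 6 correlated best with its own number, so a shared shift of same-numbered libraries was not seen. Opposite deviations, largest for the replicates 1, do not exclude a factor tied to the number. Small changes can be missed at these depths, spreads and replicate numbers together: in the simulation 32.7% of 1.3-fold changes were recovered. That simulation had fewer changed genes than were called here and no axis tied to transcript length, so the share can differ in the real data.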

Other observations

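Tests of splits, neighbours, normalization, length and GC content were fixed before their results were seen. The tests of tissue share, silique stage with its 2 parts and the genes of the genotype, and the comparison of product families, were chosen after the results were seen.

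Among 202 families of at least 10 tested genes with the same reference product name, 12 held more higher genes and 6 more lower genes than the rest (Fisher's exact test, Benjamini-Hochberg adjusted over 404 tests). These tests, and those of late embryogenesis abundant genes below, used the fit without the length correction. Fisher's test also treated close copies as independent genes, which can make its p-values too small. Of 50 GDSL lipase genes, enzymes of cutin and surface lipids among them, 13 were higher and 3 lower (odds ratio for higher calls 6.91, adjusted p = 0.000112), led by AT1G71250 (0.74) and AT1G54020 (1.87). Of 16 dirigent-like genes, 6 were higher (odds ratio 11.7, adjusted p = 0.00285), and of 28 peroxidase genes 8 were higher and 3 lower (odds ratio 7.84, adjusted p = 0.00184), the lower ones led by AT5G51890 (−1.09). Of 20 Pollen Ole e 1 and extensin genes, 7 were higher (odds ratio 10.5, adjusted p = 0.00167).

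Of 14 cytidine deaminase genes, 6 were lower (odds ratio 17.8, adjusted p = 0.00088), 5 of them adjacent in name on chromosome 4, such as AT4G29570 (−0.79) and AT4G29640 (−0.95), where close copies leave the split of reads uncertain. Of 68 glycosyltransferase genes 10 were lower and 2 higher (odds ratio for lower calls 4.103, adjusted p = 0.0125). Single genes chosen because their values were low include the glycosyltransferase genes AT4G14090 (−1.18) and UF3GT (−1.13) and the malonyltransferase gene AT5MAT (−1.22), which are not a tested group. Of 61 genes named late embryogenesis abundant, 10 were higher and 1 lower, with a median of 0.15, but 30 of them are hydroxyproline-rich glycoproteins by product name, of which 1 was higher. Of the other 31, 9 were higher and 1 lower, including M10 (1.43) and LEA18 (0.71).

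The lower lignin and secondary wall list was weighed against technical and tissue explanations. Transcript length and GC content as whole causes are argued against: the list's median was −0.57 after the length correction and −0.52 after the GC correction. Relative to all genes it stayed at −0.52 or below under 4 scalings, but a scaling shifts all genes nearly alike, so this difference could hardly move. Without that subtraction the median was −0.53 with TMM, −0.53 with DESeq2 size factors, −0.52 with upper-quartile scaling and −0.49 with library totals. The choice among these 4 scalings is argued against as its whole cause. A smaller share of silique wall, with more seed, would raise seed transcripts. The embryo storage list had a median of −0.17 (95% bootstrap interval −0.28 to −0.09). That interval resampled the list's genes, so it does not measure the spread between libraries. With the 10 most abundant genes left out the median was −0.12 (camera adjusted p = 0.791). The seed coat and endosperm list had a median of 0.04 and the late embryogenesis abundant set one of 0.15, so the tissue share stays open. Later siliques could lower both wall and storage genes, and the late embryogenesis abundant set was higher (camera p = 2.26e-05, p = 0.0498 with an estimated correlation), as were its 31 members other than hydroxyproline-rich glycoproteins (camera p = 7.96e-09, p = 0.0154 with an estimated correlation). The cell cycle list goes against a later stage, with a median of 0.16 (camera adjusted p = 0.0333, and adjusted p = 0.205 with an estimated correlation). With limma voom its median was 0.13 (camera adjusted p = 0.0529). With sets that point in opposite ways the stage stays open, and only a later stage was tested.

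SHP2 and MRPL1 were not lower in the mutant-labelled libraries. Reads of SHP1 placed on SHP2 are argued against, since SHP2 stood at 102 CPM or more in these libraries, above the 43.5 CPM of the highest WT library for SHP1. A single mislabelled library is argued against by SHP1, whose lowest WT level lay 6.01 CPM above its highest level in the mutant-labelled libraries. Alleles that still give transcript, or another genotype in all 3 libraries, may each leave SHP2 at a log2 fold change of −0.0126. These cannot be told apart with 1 count per locus and no reads over the mutated sites. Antisense reads, which the SHP2 count can include without a stated strand setting, were not tested.

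A mutant line can carry chromosome segments of another accession beside its mutations, which would put more called genes near SHP1 and near SHP2 with MRPL1. The odds ratio there was 0.81, with an interval that reaches above 1, so an excess was not seen and a small one could not be excluded. As to chance, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one with 1865 genes, gave as many calls; the highest of the others gave 1381, and 10 splits are too few for a share under 0.05. That other split set WT replicate 1 with mutant-labelled replicates 2 and 3, and points to a second structure among the samples: the second principal component, with 22.5% of the variance, had loadings that correlated with transcript length across genes (Spearman's rho −0.54).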
